A study of Chlamydomonas reinhardtii with 8 samples.

How the data were processed

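Polyadenylated RNA of 8 Chlamydomonas reinhardtii libraries had been sequenced without keeping the strand, per the labels' protocols. The labels put 2 libraries into each of 4 groups: vegetative growth, cell wall regeneration, pseudo-zygotes and early zygotes. The strain of each library was copied from the labels. The labels number no replicates, so the numbers 1 and 2 used here only name the libraries.

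The submitters' processing notes name STAR 2.4.1d and Cuffdiff 2.2.1. Per the file headers, the authors ran Cuffdiff with each library as a condition of its own and with correction for fragments that map to several places, against gene models of the v5.5 annotation. The estimated counts used here are the raw fragments per gene that Cuffdiff reported, per the file headers, with no scaling between libraries. Of these estimated counts in the deposited table, 0.853% were not whole as printed there, with no tolerance, in 249 genes, and they were rounded before testing. The FPKM values are those the authors deposited, computed after each library had been divided by its own scale factor. That scale factor is a score per library in the deposited run information, and the raw fragments of the zygote libraries had been divided by 0.540 and 0.584. The total fragment mass per library, a signal as the authors deposited it, was used only to give the share of fragments that fell in genes, which lay between 93.5% and 96.6%. Values per transcript isoform, scaled counts and the variance model of Cuffdiff, which was made without replicates, were not used here. The deposited counting carries no strand, so overlapping and antisense genes cannot be separated, and genes with near-identical copies are uncertain.

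Libraries held between 11631280 and 27174326 fragments in genes. A count of 3 fragments, the most that a count of 0 allows, corresponded to 0.110 to 0.258 CPM (counts scaled to the library total) before TMM scaling. Intervals and floors cover counting error only. The libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 86.5 for vegetative growth, 110 for cell wall regeneration, 269 for zygotes and 358 for pseudo-zygotes, so no library was treated as a repeat of another. Nothing in the labels says that the libraries of a group came from separate cultures of one strain. They came from different strains or crosses, so the p-values measure the spread between these libraries, strain differences included.

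Of 17741 genes in the table, 15513 passed edgeR's filterByExpr and were tested. TMM factors were computed with edgeR 4.0.16 in R 4.3.3. They were 0.623 and 0.684 in the zygote libraries and between 1.07 and 1.37 in the others. CPM values in the text are scaled by these factors. The quasi-likelihood test of edgeR (glmQLFit and glmQLFTest, two-sided) was fitted on all 8 libraries in 4 groups, without a block, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 0.530 and the prior degrees of freedom were 3.25. Genes of the zygote programme had to be called, with an absolute log2 fold change of at least 1, in the same direction in 4 comparisons: pseudo-zygote and zygote, each against vegetative and against cell wall regeneration. Fitted log2 fold changes depend on a prior count of 0.125 and are no bound for genes near 0. Folds of named genes were computed from the fragments summed over each group and its summed TMM-scaled library sizes, so they can differ from the ratio of the mean CPM values printed beside them. Where a group held 0 fragments of a gene, the fold was computed against 3 fragments over the group and is given as a lower bound, which falls by its construction when a library at 0 is left out. Where it held 1 to 3, the ratio is given with its exact 95% counting interval.

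The procedure was tested on simulated data, with counts drawn for the 15513 genes and 100 genes changed 4-fold and 100 changed 16-fold. Of the 16-fold changes, 74 were recovered for cell wall regeneration against vegetative, 70 for pseudo-zygote against vegetative and 67 for zygote against vegetative. Of the 4-fold changes, 4, 4 and 2 were recovered for the same comparisons in that order, with 5, 5 and 8 false calls.

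The text names genes by a rule. Among called genes with a mean of at least 10 CPM in the higher group and with all libraries of one group above all of the other, the top 2 by log2 fold change in each direction are named, and for the programme the top 2 by the smallest of the 4 changes. The rule also named GSM1, GSP1, zygote markers, gamete genes and genes of fixed lists by symbol. Of the gene identifiers, 17738 matched a locus tag of the reference table, which gave 0 symbols other than the locus tags. The 19 gene lists therefore matched no gene, their tests were not run, and genes are given by identifier. Coordinates are those of the reference table, matched by locus tag. They were assumed to be on the same assembly as the v5.5 gene models of the deposited table.

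The vegetative and cell wall regeneration libraries share the strain labels JL-I2-152 and JL-R9-53, so the labels pair them. As a check of this pairing, the deviations from the group means were correlated across the 15513 genes, taking same-labelled libraries together. The correlation was -0.689 between vegetative growth and cell wall regeneration. Matched on mating type, it was -0.018 between vegetative growth and pseudo-zygotes and -0.046 between cell wall regeneration and pseudo-zygotes.

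Alternatives were the size factors of DESeq2 within edgeR, no scaling beyond total counts, DESeq2 1.42.0, limma 3.58.1 with a trend on log2(FPKM + 1), no low-count filter, a filter of at least 1 CPM in at least 4 libraries, a fold threshold or none, only the 4 libraries compared, strain or mating type as a block, and leaving out each library. Where that left a group with 1 library, the lone library was assumed to vary like the other groups. The overlap of pseudo-zygote and zygote calls was set beside 20 simulations of unchanged groups against the same vegetative libraries, and 20 in which only pseudo-zygotes were unchanged from vegetative cells. Neighbouring genes were counted against 10000 random draws matched on expression level, over the 15370 tested genes with a position on a chromosome, with Python 3.11.15.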

Results

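RNA sequencing was used to follow gene expression in Chlamydomonas reinhardtii, a unicellular green alga whose haploid cells occur in the mating types plus (mt+) and minus (mt-). When gametes of opposite mating type fuse, the homeobox proteins GSP1 and GSM1, each brought in by one gamete, pair and start the zygote programme. The 8 libraries fell into 4 groups of 2. Vegetative cells were grown in liquid acetate medium and the other samples on agar plates, under constant light of 90 µmol per m² per s. The vegetative and the cell wall regeneration group each held a library labelled JL-I2-152, a haploid mt- strain, and a library labelled JL-R9-53, an mt+/mt- diploid. Pseudo-zygotes were cells of JL-M2MP-10 (mt-) and of JL-N7RM-110 (mt+/mt-), which expressed GSM1, GSP1 or both out of place while starved of nitrogen. Zygotes came from gametes made by 24 h without nitrogen, harvested 30 min and 2 h after mixing, and each cross joined a laboratory strain to a natural isolate (CC-125 with CC-2342, and CC-2937 with CC-621). The labels give both harvest times for each zygote library and do not say which cross was harvested when, or whether both harvests were pooled.

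The libraries held 25605931 and 11631280 fragments in genes for vegetative growth, 25203337 and 25719244 for cell wall regeneration, 27174326 and 24603887 for pseudo-zygotes, and 20150525 and 19038390 for zygotes. On the first principal component, with 48.3% of the variance, the zygotes lay at 166 and 146, the pseudo-zygotes at -1.92 and 40.5, and the vegetative and cell wall regeneration libraries between -103 and -76.8. On the second, with 19.2%, the pseudo-zygotes lay apart at -123 and -87.8. Across genes, which are not independent replicates, the log2 CPM of the zygote libraries correlated at 0.872 with each other, against 0.844 for the pseudo-zygotes, 0.940 for vegetative growth and 0.946 for cell wall regeneration.

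**Figure D1:**
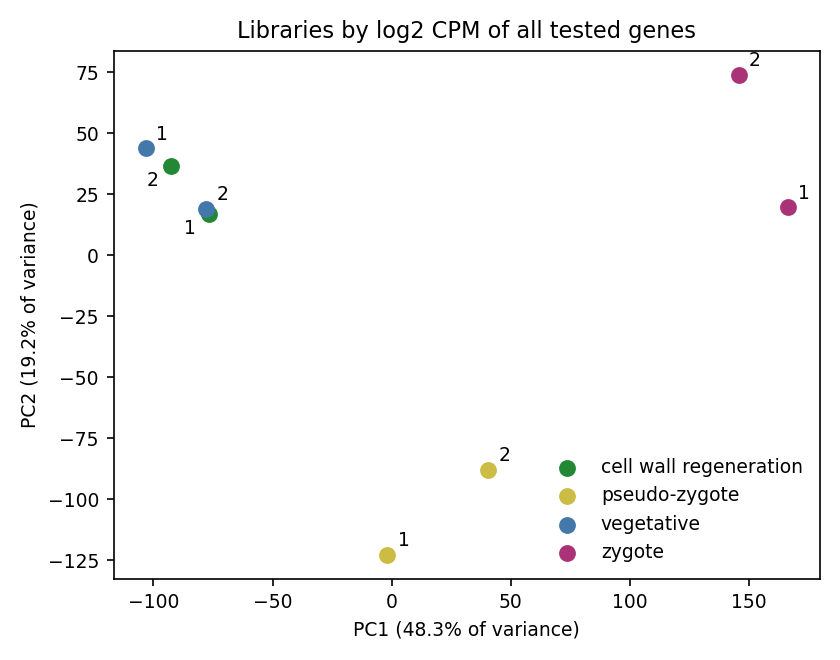
Principal components of log2 CPM over 15513 tested genes, with 1 point per library, its colour giving the group and its number the library. The first component (48.3% of variance) places the zygotes at 146 and 166, and the second sets the pseudo-zygotes, at -123 and -87.8, apart from the other groups.

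Early zygotes differed widely from vegetative cells: 1627 genes rose and 1167 fell. The genes that rose, higher by their selection, held 21.6% and 20.7% of the fragments of the vegetative libraries and 48.4% and 51.8% of those of the zygotes, while the genes that fell went from 8.47% and 6.90% to 0.523% and 0.607%. Cre06.g256800.v5.5 (chromosome 6, 1113266 to 1115907) held 0 fragments in both vegetative libraries and 933 ± 143 CPM in zygotes (mean ± SD, n = 2), at least 14500-fold higher. The next gene named by the rule, Cre06.g256850.v5.5 (chromosome 6, 1116206 to 1119317), rose from 1 fragment to 1135 ± 617 CPM, 53600-fold with a 95% counting interval of 9610 to 2120000. Without zygote library 2 that was 32800-fold, without vegetative library 1 it was 18200-fold, and without vegetative library 2, which held the fragment, at least 11800-fold. Of the genes that fell, Cre16.g661750.v5.5 (chromosome 16, 2615285 to 2618986) went from 89.6 ± 84.0 CPM to 0 fragments, at least 602-fold lower (257-fold without vegetative library 2, 1270-fold without library 1), and Cre06.g284600.v5.5 (chromosome 6, 5473585 to 5475623) from 103 ± 62.1 to 0.0398 ± 0.0563 CPM.

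In edgeR's quasi-likelihood test the adjusted p was 0.00406 for Cre06.g256800.v5.5, 0.00323 for Cre06.g256850.v5.5, 0.00842 for Cre16.g661750.v5.5 and 0.00406 for Cre06.g284600.v5.5. With total counts as the only scaling, 884 genes were higher and 4035 lower, so 18.0% of calls were higher in place of 58.2%, and the median log2 fold change over all genes lay at -1.01. DESeq2 called 4688 genes, and edgeR on the 4 libraries compared called 1722. Without vegetative library 1 no gene was called by edgeR, although 3368 passed an unadjusted p of 0.05, and none of these named genes kept its call, each with an adjusted p of 0.0601. There were 444 calls without vegetative library 2, and 1318 and 1329 without cell wall regeneration library 1 and 2.

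Genes that were off in the reference cells and on in zygotes formed a smaller group. Of 3315 genes under 1 CPM in all 4 vegetative and cell wall regeneration libraries, 92 reached at least 10 CPM in both zygote libraries, 36 did so in both pseudo-zygote libraries and 29 in all 4. In the other direction, 6365 genes held at least 10 CPM in all 4 reference libraries, and 27 of them lay under 1 CPM in both zygotes and 5 in both pseudo-zygotes. These are counts of levels, with no test.

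In pseudo-zygotes, which the design uses to find what the homeobox proteins switch on without a fusion of gametes, 131 genes rose and 37 fell against vegetative cells. Nitrogen starvation, growth on plates and strain also separate these groups, so the changes cannot be assigned to the homeobox proteins. The rule named the same genes as in zygotes. Cre06.g256800.v5.5 rose from 0 fragments to 36.0 ± 3.08 CPM (mean ± SD, n = 2), at least 560-fold, and Cre06.g256850.v5.5 from 1 fragment to 70.8 ± 15.3 CPM, 3280-fold with a 95% counting interval of 588 to 130000 (1120-fold without vegetative library 1, at least 721-fold without library 2). Cre16.g661750.v5.5 fell 667-fold to 0.112 ± 0.112 CPM, and Cre06.g284600.v5.5 fell 391-fold to 0.287 ± 0.244 CPM. These sizes rested on single libraries. The fall of Cre16.g661750.v5.5 was 1410-fold and 285-fold without vegetative library 1 and 2, and 370-fold and 2150-fold (95% counting interval 386 to 85000) without pseudo-zygote library 1 and 2. The fall of Cre06.g284600.v5.5 was 198-fold without vegetative library 1, and 1030-fold (351 to 4980) and 255-fold without pseudo-zygote library 1 and 2. In cell wall regeneration Cre16.g661750.v5.5 held 3.1 ± 2.0 CPM, which edgeR's quasi-likelihood test did not call lower than in vegetative cells (adjusted p 0.533). By the same test it was lower in zygotes than in cell wall regeneration (adjusted p 0.032). Pseudo-zygotes also lay below cell wall regeneration but missed the threshold (0.107). Whether its fall is particular to zygotes and pseudo-zygotes therefore stays open.

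The adjusted p of edgeR's quasi-likelihood test was 0.0313 for Cre06.g256800.v5.5, 0.0242 for Cre06.g256850.v5.5, 0.0426 for Cre16.g661750.v5.5 and 0.0254 for Cre06.g284600.v5.5, and 3400 genes passed an unadjusted p of 0.05. The number of calls depended on the fit: DESeq2 called 2172 genes and limma on FPKM 469, while edgeR called 0 on the 4 libraries compared (3485 at an unadjusted p of 0.05) and 0 with mating type as a block (3410), and in neither fit was any of these named genes called. With the strain labels of the cell wall regeneration libraries exchanged, an alternative added after the data were seen, the same block gave 100 calls, among them Cre06.g256850.v5.5 (adjusted p 0.0396) and Cre06.g284600.v5.5 (0.0353). With total counts as the only scaling, 63.8% of the calls were higher in place of 78.0%. No gene was called by edgeR without vegetative library 1 or without vegetative library 2, where 1492 and 2214 genes passed an unadjusted p of 0.05. There were 30 calls without either cell wall regeneration library, and 503 and 547 without zygote library 1 and 2. Several of the named genes also lost their call without 1 of the pseudo-zygote libraries: Cre06.g256800.v5.5 had an adjusted p of 0.0503 and 0.0557 without pseudo-zygote library 1 and 2, and Cre16.g661750.v5.5 had 0.0960 and 0.0781. That of Cre06.g284600.v5.5 was 0.0531 without pseudo-zygote library 2. Without cell wall regeneration library 1 and 2, that of Cre16.g661750.v5.5 was 0.0888 and 0.0850, and that of Cre06.g284600.v5.5 was 0.0519 and 0.0518.

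Against vegetative cells, 106 genes rose in both pseudo-zygotes and zygotes and 23 fell in both, while independent lists of these sizes would share 13.7 and 2.78. Nitrogen starvation and growth on plates separate both groups from vegetative cells, so they could also raise this overlap. Of the 1627 genes that rose in zygotes, 1216 (74.7%) had a fitted change of the same direction in pseudo-zygotes, as had 1017 (87.2%) of the 1167 that fell. With zygotes set against cell wall regeneration, so that no library was shared, these shares were 70.1% of 1520 and 75.8% of 1197. The vegetative and cell wall regeneration groups carry the same strain labels, so strain effects common to them could still raise the agreement with no shared library. The simulations below do not cover such effects, since they set pseudo-zygotes unchanged from vegetative cells. Both comparisons use the same vegetative libraries, so these values were set beside simulations. With zygotes and cell wall regeneration at their fitted levels and pseudo-zygotes unchanged from vegetative cells, the shares of the same direction averaged 60.2% and 61.6% against vegetative cells, at most 62.8% and 63.8% in 20 simulations, and 49.7% and 49.4% with no shared library. EdgeR's shared calls were 0 in each of these simulations. An unchanged group gives few calls by its construction, so that 0 does not bear on whether the response is shared. At an unadjusted p of 0.05 in pseudo-zygotes, 618 of the genes higher in zygotes were higher and 408 of those lower were lower, against means of 111 and 92.8 in these simulations. An unchanged group also passes few genes at that threshold, so these means do not bear on whether the response is shared either. The covariance of the log2 fold changes across genes was 2.07, against 0.366 in 20 other simulations, of unchanged groups against these libraries, a difference of 1.70. The correlation was 0.559 against 0.505 in the simulations, and 64.1% of genes had the same sign against 66.7%. With no shared library, 84 genes rose in both and 19 fell in both, where independent lists would share 12.8 and 2.85, and the covariance was 1.68. The 129 shared calls became 1020 by DESeq2 and 278 by limma, and 47 without both cell wall regeneration libraries. By edgeR they were 0 without either vegetative library, 30 without either cell wall regeneration library, and 227 and 305 without zygote library 1 and 2.

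**Figure D2:**
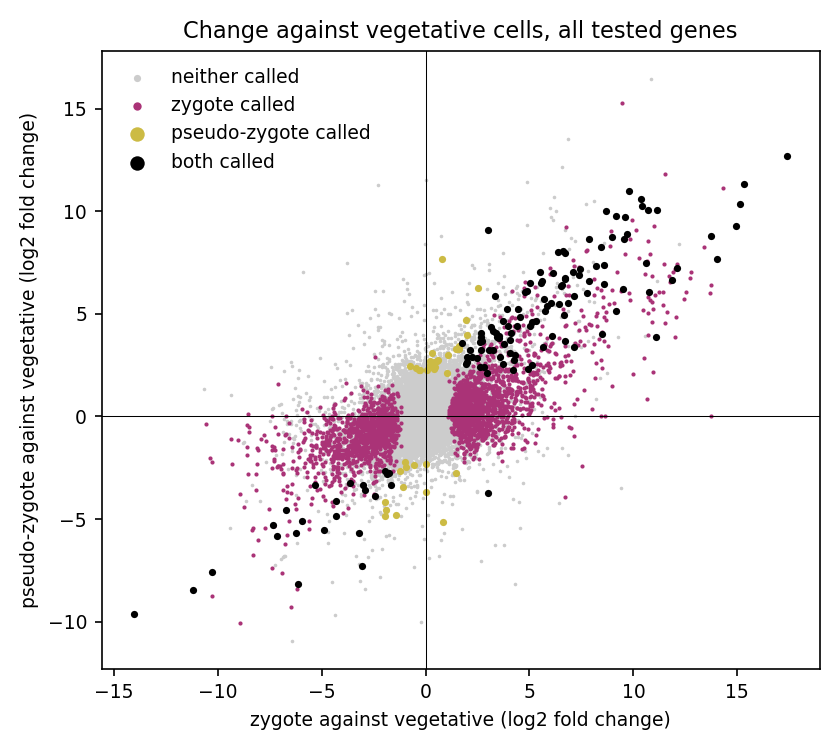
Fitted log2 fold change against vegetative cells of 15513 genes in zygotes (horizontal axis) and pseudo-zygotes (vertical axis), with 1 point per gene and colours for genes called in neither, either or both. The genes called in both lie in the upper right (106) and the lower left (23), apart from 1 that fell in pseudo-zygotes and rose in zygotes.

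Zygotes and pseudo-zygotes themselves differed in 2329 genes, of which 1225 were higher and 1104 lower in zygotes. Since the vegetative libraries are shared, this is also the test of whether the 2 changes against vegetative cells differ. Of the 1627 genes that rose in zygotes 894 were called here, as were 448 of the 1167 that fell. Cre15.g642950.v5.5 (chromosome 15, 1904098 to 1906677) held 74.0 ± 20.5 CPM in zygotes (mean ± SD, n = 2) and 0 fragments in pseudo-zygotes, vegetative cells and cell wall regeneration, at least 1390-fold higher than in pseudo-zygotes. Cre12.g492150.v5.5 (chromosome 12, 642615 to 644996) held 64.5 ± 83.4 CPM in pseudo-zygotes and 0 fragments in zygotes, at least 587-fold lower. This rests mostly on pseudo-zygote library 1, with 124 CPM against 5.49 CPM in library 2, and the bound is 46.8-fold without library 1 and 1050-fold without library 2. The other gene named in each direction also rested mostly on 1 library. Cre13.g563500.v5.5 (chromosome 13, 199283 to 210078) held 346 CPM in zygote library 1 and 0.0768 CPM in zygote library 2, against 1 fragment in pseudo-zygotes. Cre17.g713100.v5.5 (chromosome 17, 2184840 to 2188155) held 39.3 CPM in pseudo-zygote library 1 and 0.458 CPM in library 2, against 1 fragment in zygotes.

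For these genes edgeR's quasi-likelihood test gave an adjusted p of 0.00846 (Cre15.g642950.v5.5), 0.0488 (Cre13.g563500.v5.5), 0.0244 (Cre12.g492150.v5.5) and 0.0431 (Cre17.g713100.v5.5). Without zygote library 1 the adjusted p of Cre13.g563500.v5.5 was 0.562, and without pseudo-zygote library 1 that of Cre17.g713100.v5.5 was 0.167. Without zygote library 1 or 2, that of Cre12.g492150.v5.5 was 0.0612 or 0.0725. Without pseudo-zygote library 1 or 2, Cre13.g563500.v5.5 was at 0.173 or 0.150, and without zygote library 1 or 2, Cre17.g713100.v5.5 was at 0.141 or 0.132. Without any one of the 4 vegetative and cell wall regeneration libraries, the calls of Cre12.g492150.v5.5, Cre13.g563500.v5.5 and Cre17.g713100.v5.5 were lost. That of Cre15.g642950.v5.5 held without each single library and was lost on the 4 libraries compared (adjusted p 0.0628), and the filter of at least 1 CPM in at least 4 libraries left it untested. On those 4 libraries edgeR called 0 genes, with 3341 at an unadjusted p of 0.05, while DESeq2 on all libraries called 4492. With total counts as the only scaling there were 3808 calls, 19.1% of them higher in zygotes in place of 52.6%. Calls numbered 985 without pseudo-zygote library 1, 1001 and 998 without vegetative library 1 and 2, and 705 and 704 without cell wall regeneration library 1 and 2.

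The zygote programme proper, in the sense of genes changed in both kinds of zygote against both references, held 57 genes that rose and 8 that fell. The 57 genes, higher by their selection, took 0.01% and 0.012% of the fragments of the vegetative libraries, 0.0119% of each cell wall regeneration library, 0.405% and 0.397% in pseudo-zygotes and 1.21% and 1.16% in zygotes. Cre17.g714150.v5.5 (chromosome 17, 2299381 to 2307236) reached 101 ± 74.0 CPM in pseudo-zygotes and 86.7 ± 55.5 CPM in zygotes (mean ± SD, n = 2), with 3 fragments in vegetative cells and 2 in cell wall regeneration. Against vegetative cells that is 1520-fold (95% counting interval 520 to 7370) and 1340-fold (459 to 6520). Without pseudo-zygote library 1 and 2 the former was 2400-fold and 764-fold, and without zygote library 1 the latter was 741-fold. The 3 fragments lay in vegetative library 1, without which the bounds were 518-fold and 457-fold, and without vegetative library 2 the folds were 1000 and 885. Cre13.g576950.v5.5 (chromosome 13, 2026696 to 2030438) rose from 1 fragment in each reference to 33.6 ± 10.3 CPM in pseudo-zygotes and 935 ± 79.7 CPM in zygotes, where it was higher than in pseudo-zygotes (27.3-fold, adjusted p 0.0089 in edgeR's test). Of the genes that fell, Cre06.g284600.v5.5 held 103 ± 62.1 CPM in vegetative cells, 54.6 ± 27.3 CPM in cell wall regeneration and under 1 CPM in every zygote and pseudo-zygote library. Cre09.g392867.v5.5 (chromosome 9, 276607 to 291842) went from 64.6 ± 43.6 and 147 ± 25.9 CPM in the references to 0.221 ± 0.173 CPM in pseudo-zygotes and 0.903 ± 0.299 CPM in zygotes.

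In edgeR's 4 tests the adjusted p of these genes ran from 0.00406 to 0.0248 for Cre17.g714150.v5.5, from 0.0029 to 0.0129 for Cre13.g576950.v5.5, from 0.00406 to 0.0362 for Cre06.g284600.v5.5 and from 0.00456 to 0.022 for Cre09.g392867.v5.5. Growth on plates also separates zygotes and pseudo-zygotes from the vegetative cells, but not from cell wall regeneration, against which the programme had to be called too. Nitrogen starvation separates them from both references as far as the labels go, so the programme cannot be told apart from the starvation response. DESeq2 gave 416 genes higher and 183 lower, and limma on FPKM 100 and 33. On the 4 libraries compared, none of the named genes was called in pseudo-zygotes against either reference. By edgeR the programme held 0 genes without either vegetative library and 0 without either cell wall regeneration library. It held 103 higher and 15 lower without pseudo-zygote library 1, 13 lower without pseudo-zygote library 2, 20 and 1 without zygote library 1, and 19 and 2 without zygote library 2. Without zygote library 1 or 2, Cre17.g714150.v5.5, Cre06.g284600.v5.5 and Cre09.g392867.v5.5 missed the threshold in pseudo-zygotes against cell wall regeneration, with an adjusted p from 0.0507 to 0.0513. That of Cre06.g284600.v5.5 was 0.0528 and 0.0599 without pseudo-zygote library 1 and 2.

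**Figure D3:**
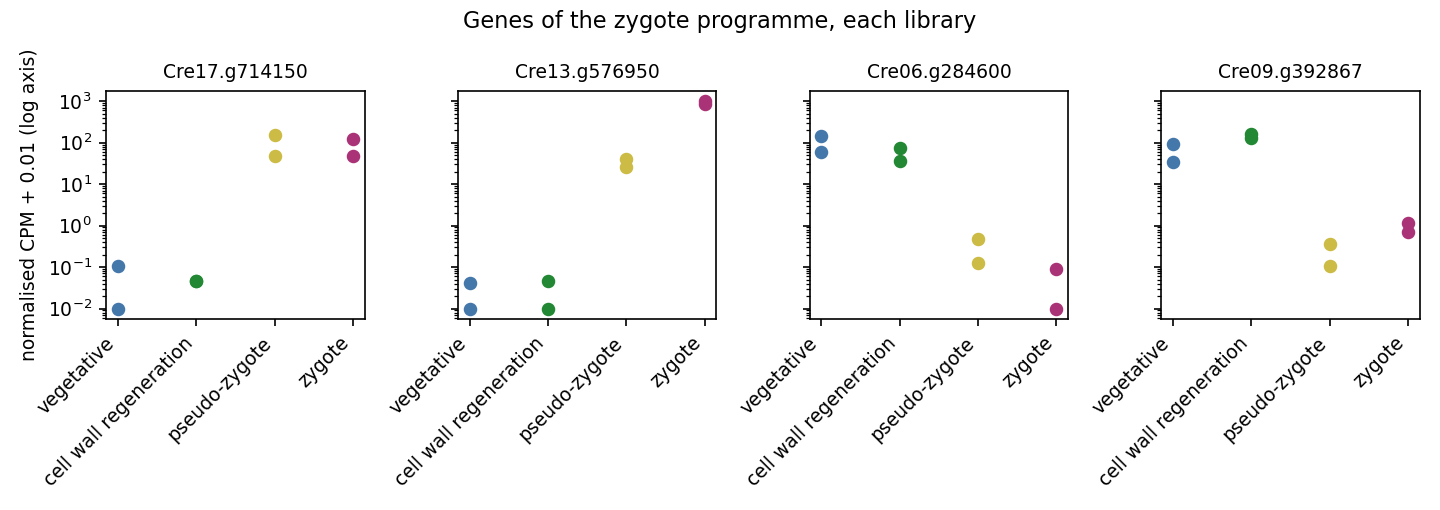
TMM-normalised CPM (plus 0.01, log axis) of the genes named for the zygote programme, with 1 point per library and 2 per group. Cre17.g714150 and Cre13.g576950 lie near 0 in the vegetative and cell wall regeneration libraries and above 10 CPM in every zygote and pseudo-zygote library, and Cre06.g284600 and Cre09.g392867 go the other way.

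The genes higher in zygotes were unevenly placed. In the window of 20 tested genes with the most of them, on chromosome 6 from 1008166 to 1128847, 12 rose against vegetative cells, against 10.5% of all genes. Both Cre06.g256800.v5.5 and Cre06.g256850.v5.5 lie there, next to each other, and 3 of the 12 were also called higher in pseudo-zygotes. In both pseudo-zygote libraries, 8 of the 12 lay at least 2-fold above each vegetative and cell wall regeneration library, a count with no test. In 1000 random placements the fullest window held a median of 8 genes higher in zygotes and at most 12, so a window this full was at the upper end of chance. Among all genes higher in zygotes, 23 of the 298 neighbouring pairs lay at least 2000 bases apart, and the libraries do not keep the strand, so reads of close neighbours may overlap. Of the 57 programme genes that rose, 3 lay within chromosome 1 from 1582006 to 1597097 with no other tested gene between them, 5 of 7 tested genes from 2304728 to 2368003 of that chromosome belonged to the programme, and so did 3 of 5 on chromosome 6 from 954072 to 981812. These runs were chosen after the values were seen.

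**Figure D4:**
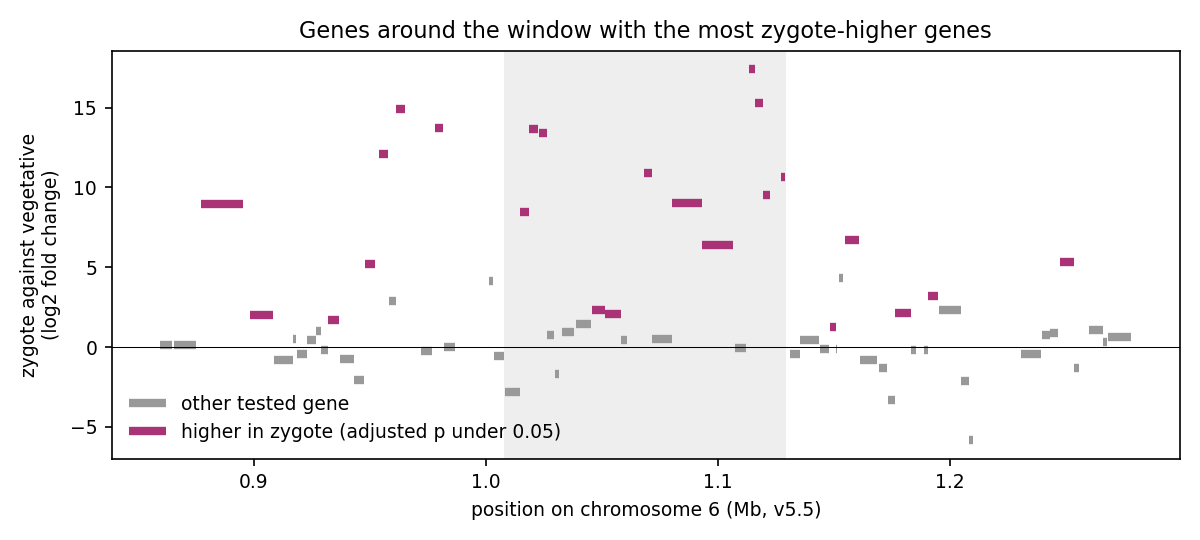
Fitted log2 fold change of zygotes against vegetative cells (vertical axis) for the tested genes around the fullest window of chromosome 6, drawn at their positions in megabases, with genes called higher in colour and the window from 1008166 to 1128847 shaded. In the window 12 of 20 genes are called higher.

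Against cell wall regeneration, which the design adds so that genes used to rebuild any wall can be told from those of the zygote, 1520 genes were higher and 1197 lower in zygotes, and 70 were higher and 17 lower in pseudo-zygotes. Cre06.g256850.v5.5 was 4530-fold higher in zygotes and 277-fold higher in pseudo-zygotes than in cell wall regeneration (edgeR adjusted p 0.00406 and 0.0362), and Cre06.g256800.v5.5 was 7370-fold higher in zygotes (0.00497) but missed the threshold in pseudo-zygotes (284-fold, 0.0535). The 7 fragments of Cre06.g256800.v5.5 in cell wall regeneration all lay in library 1, and without library 2 the folds were 3730 and 144. Those of Cre06.g256850.v5.5 were 15700 and 959 without cell wall regeneration library 1, with 95% counting intervals of 4330 to 129000 and 265 to 7920, and 2670 and 163 without library 2, and in zygotes 2770 without zygote library 2. Cre06.g257950.v5.5 (chromosome 6, 1247373 to 1253425), chosen after its values were seen, rose against vegetative cells in zygotes (260 ± 122 against 6.50 ± 0.692 CPM, mean ± SD, n = 2, adjusted p 0.00416) and in pseudo-zygotes (165 ± 58.0 CPM, 0.0267). It held 128 ± 56.8 CPM in cell wall regeneration, from which neither differed by the test (0.206 and 0.72). Only the vegetative cells, in which it was low, grew in liquid medium. Growth on plates therefore cannot be told from wall rebuilding for this gene.

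For zygotes against cell wall regeneration DESeq2 called 4713 genes and edgeR on the 4 libraries compared 1703, and with total counts as the only scaling 23.4% of calls were higher in place of 55.9%. Calls fell to 7 and 5 without cell wall regeneration library 1 and 2, and to 1401 and 1404 without vegetative library 1 and 2. For pseudo-zygotes the 87 calls became 2026 by DESeq2 and 346 by limma. EdgeR called 0 on the 4 libraries compared, with 3416 genes at an unadjusted p of 0.05, and 0 without cell wall regeneration library 1 or 2, with 1843 and 1481. There were 152 and 200 calls without pseudo-zygote library 1 and 2, 17 without either vegetative library, and 25 and 24 without zygote library 1 and 2.

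Between cell wall regeneration and vegetative growth no gene passed the test, and the genes with the smallest unadjusted p in each direction are given as values. They were chosen after the values were seen. Vegetative cells grew in liquid medium and the other groups on plates, so wall rebuilding and growth on plates cannot be told apart in this comparison. Cre12.g495450.v5.5 (chromosome 12, 757512 to 760514) held 220 ± 84.8 CPM in cell wall regeneration and 15.1 ± 6.43 CPM in vegetative cells (mean ± SD, n = 2), with 17.1 ± 2.69 CPM in pseudo-zygotes and 14.7 ± 0.459 CPM in zygotes. Cre06.g257950.v5.5 held 128 ± 56.8 against 6.50 ± 0.692 CPM. In the other direction, Cre09.g394473.v5.5 (chromosome 9, 4243439 to 4250404) held 51.5 ± 25.4 CPM in cell wall regeneration against 372 ± 93.6 CPM, and Cre02.g091200.v5.5 (chromosome 2, 2392965 to 2398834) held 22.9 ± 2.56 against 77.4 ± 2.90 CPM.

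By edgeR's quasi-likelihood test 0 genes were called and the smallest adjusted p was 0.373, with 697 genes at an unadjusted p of 0.05, of which 475 were higher in cell wall regeneration. DESeq2 called 150, of which 116 were higher, and limma called 0. The libraries labelled with the same strain correlated at 0.906 (JL-I2-152) and 0.913 (JL-R9-53) across genes, and those labelled with different strains at 0.952 and 0.944. With strain as a block as labelled, edgeR called 0 genes (976 at an unadjusted p of 0.05). With the strain labels of 1 pair exchanged, an alternative added after the data were seen, it called 1776.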

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

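The gene sets, thresholds, groups and main test were fixed before the data were examined. The tests of the strain labels, of strain as a block with exchanged labels and of the shallow vegetative library were chosen only after the result was seen.

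The change against vegetative cells differed between zygotes and pseudo-zygotes in 2329 genes by edgeR's test of the difference itself, which drew attention because the groups differed under the same contrast. Strain, gamete formation and harvest after mixing also separate these groups, so the differences cannot be assigned to a single cause. In 28 of them both changes were called, and in 1452 the fitted changes had opposite signs. Calls numbered between 704 and 2697 when single libraries were left out, lowest without cell wall regeneration library 2.

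In 1 gene both changes were called in opposite directions. Cre06.g286100.v5.5 (chromosome 6, 5644020 to 5649675) was outside the rule for named genes and was chosen after its values were seen. It held 3.08 and 3.20 CPM in vegetative cells, 0.197 and 0.267 CPM in pseudo-zygotes and 20.9 and 29.7 CPM in zygotes. In cell wall regeneration it held 0.785 and 0.839 CPM, also below vegetative cells. Against vegetative cells that is a fall of -3.73 ± 0.47 in pseudo-zygotes (log2 fold change ± SE, adjusted p 0.0259) and a rise of 3.01 ± 0.43 in zygotes (0.0067). Each SE was computed back from the fold change and the F value of edgeR's quasi-likelihood test. The changes differed by 6.74 ± 0.52 (0.00644).

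The strain labels of the vegetative and cell wall regeneration libraries ran against the expression values. Of 30 genes at 10 CPM or more in 1 vegetative library and under 1 CPM in the other, 24 were at least 4-fold apart between the cell wall regeneration libraries in the direction opposite to the labels and 0 in the direction of the labels. That count restates the pattern and does not say which labels are wrong, so chromosome 6 genes chosen from the pseudo-zygotes alone were read. Other chromosomes were not read, although genes at 10 CPM or more in the diploid and under 1 CPM in the haploid pseudo-zygote library lay there too. There were 9 on chromosome 12, 8 on chromosome 11 and 7 on chromosome 8, among others, against 7 on chromosome 6. On chromosome 6 lay 9 genes between 74866 and 565860, each within 200000 bases of another, that held at least 10 CPM in the diploid pseudo-zygote library, at least 16-fold above the haploid one. Strain labels that are correct in both groups went against 4 of them, which were at least 4-fold higher, with at least 1 CPM, in the cell wall regeneration library labelled with the haploid JL-I2-152 than in the one labelled with the diploid, and 0 the other way. An exchange that lies in the vegetative pair went against 5 of them, which were higher in the vegetative library labelled with the diploid, and 0 the other way. Cre06.g252892.v5.5 and Cre06.g253051.v5.5, chosen after their values were seen, held 15.1 and 19.1 CPM there against 0.0971 and 0.162 CPM, and 13.1 and 26.9 CPM in cell wall regeneration library 1 against 0.146 and 0.0365 CPM in library 2. The remaining genes decide nothing, since they differed by less or lay under 1 CPM, and Cre06.g252550.v5.5 was on in all 4 libraries. A candidate explanation is that the strain labels of the cell wall regeneration pair were exchanged, by the same 4 and 5 genes. This assumes that the genes mark the diploid in growing cells too, with 1 library per strain and few genes that are close neighbours, and mixed cultures were not tested and stay open. A first version of the test, on the 5 of these genes from 448835 to 565860 that lay under 1 CPM in the haploid pseudo-zygote library, found 2 of 5 against the cell wall regeneration labels and 3 of 5 along the vegetative labels, 0 the other way in each, short of the majority it needed for the former, and was replaced. The version used here needed at least 4 of the 9 genes and 0 the other way, less than a majority. That bar was set after the result was seen, so the counts give a direction and do not decide which labels are wrong.

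No gene was called by edgeR between cell wall regeneration and vegetative growth, against 697 at an unadjusted p of 0.05, 150 by DESeq2 and 0 by limma. A candidate explanation is that strain differences were counted as spread between replicates. With the exchanged strain as a block 1776 genes were called, 1053 higher and 723 lower, and these held 148 of DESeq2's 150 with the same sign. That pairing was inferred from these same libraries, so the block had to lower the spread and cannot test this explanation. The overlap with DESeq2 rests on the same counts and adds no support. The shallow vegetative library 2, with 11631280 fragments, was argued against as the whole cause: among the 9039 genes with at least 100 fragments in each of the 4 libraries, the fit without a block called 0 too, with 409 at an unadjusted p of 0.05 and a smallest adjusted p of 0.416. For genes with fewer fragments depth stays open. The 1776 calls rest on an exchange of labels inferred from these libraries, so they are no independent evidence of a response to wall loss. Which genes respond stays open while the strain of each library is not known. Growth also separates these groups, with vegetative cells in liquid medium and cell wall regeneration on plates. Known strains alone would therefore not tell a response to wall loss from a response to plates.

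Genes higher in zygotes lay next to each other more often than by chance. There were 298 neighbouring pairs among 1620 such genes, against a mean of 179 and at most 225 in 10000 random draws matched on expression level. That count is the pattern itself, so joint expression of neighbouring genes in zygotes and read-through cannot be told apart by it. Reads shared between near-identical copies were argued against by 294 pairs that were left without the genes with fractional counts, above the highest draw of 226. Variants of the natural isolates were argued against for only part of these genes. The 322 that were also at least 2-fold higher in both pseudo-zygote libraries, whose labels name no natural isolate, than in each vegetative and cell wall regeneration library held 28 neighbouring pairs, against a mean of 7.04 and at most 20 in the draws. For the other genes such variants stay open. Overlap or read-through between adjacent genes stays open too, because the 23 pairs at least 2000 bases apart lay at the random mean of 22.7, so the excess came from close pairs and may be partly technical in these libraries without strand.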

How the results depend on the processing

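Tests with an exchanged strain label and those without both cell wall regeneration libraries were chosen only after the result was seen. Of the counts of calls, 26 rose and 50 fell by over 1.5 times under an alternative, while 73 stayed within that range. For the genes named by the rule, those of the programme in each of its 4 comparisons, 309 of 417 values stayed past the threshold, 108 lost the call and 0 reversed. The genes that a filter removed have no value there. DESeq2's size factors in edgeR, the filters on low counts and the fold thresholds moved no count by over 1.5 times. The tests of gene lists (camera and fry) were not run, because no list matched a gene. The cause of the changes below was not tested, except that fits on fewer libraries have fewer degrees of freedom.

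With total counts only, 4919 genes were called for zygote against vegetative and 3808 for zygote against pseudo-zygote. DESeq2 called 150 for cell wall regeneration against vegetative, 2172 for pseudo-zygote and 4688 for zygote against vegetative, 2026 and 4713 for the same against cell wall regeneration, and 4492 for zygote against pseudo-zygote, with 416 programme genes higher, 183 lower and 1020 shared calls. Limma on log2(FPKM + 1) gave 469 for pseudo-zygote against vegetative, 346 against cell wall regeneration, 100 programme genes higher, 33 lower and 278 shared calls. On only the 4 libraries compared, edgeR called 0 for pseudo-zygote against vegetative, against cell wall regeneration and against zygote (3485, 3416 and 3341 at an unadjusted p of 0.05), 1722 for zygote against vegetative and 1703 against cell wall regeneration. Without both cell wall regeneration libraries there were 47 calls for pseudo-zygote and 1397 for zygote against vegetative, 754 between them, and 47 shared calls.

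With strain as a replicate block as labelled, edgeR called 0 genes for cell wall regeneration against vegetative. With mating type as a block, 0 were called for pseudo-zygote against vegetative (3410 at an unadjusted p of 0.05), and the same-labelled libraries did not deviate together. Crossing the pairing of vegetative and cell wall regeneration libraries, added after seeing the data, gave 1776 calls for cell wall regeneration. With the cell wall regeneration labels exchanged and the others kept, the mating-type block gave 100 for pseudo-zygote against vegetative.

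Leaving out single libraries, edgeR calls ranged from 0 to 0 for cell wall regeneration (309 to 1118 at an unadjusted p of 0.05), 0 to 547 for pseudo-zygote and 0 to 3331 for zygote against vegetative, 0 to 200 and 5 to 3294 for the same against cell wall regeneration, and 704 to 2697 between them. Programme genes ranged from 0 to 103 higher and 0 to 15 lower, and shared calls from 0 to 305. Against vegetative growth the zeros came without vegetative library 1 or 2 for pseudo-zygotes and shared calls, and without 1 for zygotes. For pseudo-zygote against cell wall regeneration they came without either cell wall regeneration library, and for the programme without any of these 4.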

Other observations

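The tests of neighbouring genes below, for genes lower in zygotes, higher in pseudo-zygotes and of the programme, were chosen only after the result for genes higher in zygotes was seen.

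Genes that fell in zygotes also lay next to each other, with 136 neighbouring pairs among 1159 genes against a mean of 87.7 and at most 124 in 10000 draws. For the 131 genes higher in pseudo-zygotes there were 9 pairs, against a mean of 1.15 and at most 8. The 57 programme genes that rose held 6 pairs, against a mean of 0.23 and at most 4. The permutation p was 0.0001 in each, the smallest that these draws can give. None of the programme pairs lay at least 2000 bases apart, where 0.02 were drawn on average.

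The library labelled JL-N7RM-110 among the pseudo-zygotes lay nearer to the zygotes than the library labelled JL-M2MP-10. Across genes its log2 CPM correlated at 0.829 and 0.775 with zygote library 1 and 2, against 0.755 and 0.718. It also correlated higher with cell wall regeneration library 1 and 2 (0.8201 and 0.7951, against 0.8005 and 0.7863). The same held for vegetative library 1 and 2 (0.7713 and 0.8113, against 0.7638 and 0.8084), so a higher correlation was not particular to the zygotes. These differences were not tested, since each strain has 1 library.

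Between vegetative cells and cell wall regeneration, 3 genes under 1 CPM in both vegetative libraries held at least 10 CPM in both cell wall regeneration libraries. This is a count of levels, with no test.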
